A study of Rattus norvegicus with 30 samples.

How the data were processed

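Gene expression was measured on 30 single-colour Affymetrix arrays, 1 per culture well, in cryopreserved male Sprague Dawley rat hepatocytes that had been thawed, plated on collagen and overlaid with Matrigel. Per the labels, wells were dosed on the third day of culture with 500 or 5000 µM acetaminophen or with 1% DMSO as vehicle and were harvested 24 or 48 h later. The 6 groups of dose and time held 5 arrays each, and the protocol describes the 5 wells of a group as independent cultures. The groups were taken from the sample titles. The titles carry no replicate numbers that pair wells, so replicates are numbered within each group only to name them.

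The deposited values are linear MAS5 signal intensities, 1 per probe set. MAS5 is named in the submitters' processing notes without a version, and scanner settings and the scaling target are not given in the sources used here. The 2% trimmed means of the arrays lay between 1500.55 and 1500.66, so a scaling of every array to one target had already been made by the authors. The values were therefore used as deposited, after a log2 transformation, with no further scaling. They had not been centred per probe set. The table held 31099 probe sets, of which 57 were control probe sets and were left out of the tests. A platform annotation named 1 gene symbol for 20832 probe sets and several for 436, and 9780 had no listed gene and are unnamed here. Symbols were updated to those of the rat RefSeq annotation through the Entrez identifiers, which matched for 20764 probe sets. No gene was named from a probe set with several symbols.

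Each gene was represented by its brightest probe set, by mean log2 signal over the 30 arrays, which gave 14217 genes. The brightest 60% of these, 8531 genes, were tested. The dimmest tested gene had a geometric mean signal of 469. One linear model with a mean per group was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3 (24 residual degrees of freedom), followed by eBayes with an intensity trend, which added 7.58 prior degrees of freedom. Fold changes are differences of group means on the log2 scale with their moderated standard errors, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The 9 comparisons were each dose against vehicle at each time, 5000 against 500 µM at each time, 48 against 24 h in vehicle, and for each dose the difference between its effects at 48 and 24 h. Where a gene named as a largest change or fixed for the compound had several probe sets, the others were compared with the chosen one. Genes named only as list members were not compared in this way. For them only the fit with the mean of all probe sets bears on this. For Cdkn1a and Mdm2 at 500 µM and 48 h, 3 other probe sets were called in the direction opposite to the chosen probe set, so these genes are not described as changed in that comparison. Scd2, Txnrd1, Elovl5 and Pex11a have other values of this kind beside theirs. Other probe sets gave values nearer 0 or of the other sign for Exoc1 (-0.28, -0.39 and -0.42) and Tti2 (-0.10 and 0.16) at 500 µM and 48 h and Atosb at 500 µM and 24 h (-0.16). They did so for Nfic (-0.28) and Tti2 (0.39 and -0.23) in the 500 µM difference between times, and for further genes not listed here.

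There were 31 gene lists, fixed before the data were examined, with 786 members, of which 694 were named on the array and 565 were tested. They covered NRF2 targets, glutathione transferases and peroxidases, AhR targets, CAR and PXR targets, other cytochrome P450 enzymes, glucuronidation and sulfation, the ATF4 and CHOP integrated stress response, endoplasmic reticulum chaperones, the heat shock response, p53 targets, cell cycle, cholesterol synthesis, fatty acid synthesis, PPAR-alpha targets and fatty acid oxidation, bile acid synthesis and transport, gluconeogenesis and glycolysis, urea cycle and amino acid catabolism, secreted hepatocyte proteins, liver-enriched transcription factors, acute phase and complement, NF-kB and inflammatory genes, oxidative phosphorylation, proteasome, ribosome biogenesis, metal response, circadian clock, hepatocyte dedifferentiation and cytoskeleton, and markers of Kupffer cells and leukocytes, stellate cells and fibroblasts, sinusoidal endothelium and cholangiocytes. A list needed 5 tested members, which 27 lists had. Lists were tested with camera in limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over all lists and the 4 comparisons of a dose with vehicle together. The lists in the comparison of vehicle wells over time, and in each difference between times, were adjusted as families of their own. The p with a correlation estimated from the data is given beside each call.

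The genes named were chosen by a rule written before the data were examined. For comparisons of one group with another it used called genes whose arrays in one group all lay above or all below those of the other. From these it took the 10 largest rises and falls at 5000 µM at each time. The 5 largest at 500 µM at each time and in vehicle over time, and the 3 largest between doses, came from them too. Among called differences between times it took the 5 largest in each direction, with no such separation required. Placeholder symbols were passed over. It also took up to 4 members per list with the smallest p at 5000 µM, and 31 genes fixed for the compound, of which 26 were tested. Mt1 was among the fixed genes but too dim, at a mean signal of 436, and its adjusted p in a limma fit without the filter (Benjamini-Hochberg) lay between 0.222 and 0.853 over the 4 comparisons of a dose with vehicle. The rule named 193 genes. A result of the comparison between doses at 48 h is not reported here. A few other genes are named as members of counts, and are marked as chosen after their values were seen.

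Control probe sets gave a measure of RNA quality, the log2 ratio of the 3' to the 5' β-actin probe sets, and likewise for GAPDH. Differences in the β-actin ratio between groups were tested with a two-sided exact permutation test over 252 arrangements, adjusted over 7 comparisons. Because the ratio differed between groups, 4 settings were added after the data had been seen: the ratio as a covariate, arrays above or below the widest gap in the ratio as a block, and only the arrays on either side of the gap. The alternatives fixed beforehand were quantile normalization, centring each array on its median, no filter on dim genes, the brightest 40% of genes, 16 added before log2, no intensity trend, only the groups compared, array weights, the mean of all probe sets of a gene, every probe set in place of genes, an adjusted p under 0.01, at least a 1.5-fold change, sets of 6 consecutive title numbers as a block, fry and an estimated correlation in place of camera, and leaving out each of the 30 arrays. Residuals of arrays in the same set of title numbers had a median correlation of 0.06, against -0.02 for arrays of different sets. No pair of arrays held identical values, and the closest pair within a group differed with an SD of 0.20 on the log2 scale against a median of 0.26.

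The fit was tested on simulated data made from the real means and spread for the comparison of 5000 µM with vehicle at 48 h over 8531 genes. Of 100 genes changed by 0.5 log2, 72 were recovered, and of 100 changed by 1 log2, 99 were recovered, with 10 false calls among 181 calls. A list shifted by 0.25 log2 was called and none of the other lists was. The simulated genes were drawn independently of each other, so this does not test list calls against correlation between genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Arrays have no read depth, so their number limits the precision.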

Results

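Transcript levels were measured in primary rat hepatocytes exposed to acetaminophen, an analgesic that is cleared in the liver by glucuronidation and sulfation and, in part, by cytochrome P450 oxidation to a reactive quinone imine that binds glutathione. Wells received vehicle (1% DMSO), 500 µM or 5000 µM acetaminophen for 24 or 48 h, with 5 wells and 5 arrays in each of the 6 groups. The study was set up as a time course and dose response, so each dose was compared with vehicle at each time, the doses with each other, and the times with each other. The wells came from one kind of purchased frozen hepatocyte, so p-values measure the spread between wells, and not between animals. Errors on log2 changes are standard errors, and adjusted p-values are Benjamini-Hochberg values from limma for genes and from its camera test for gene lists, with n = 5 arrays per group throughout. For each gene named as a largest rise or fall, all 5 arrays of one group lay beyond all 5 of the other.

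RNA quality, measured as the log2 ratio of the 3' to the 5' β-actin control probe sets, differed between groups. At 24 h it was 1.78 ± 0.24 (SD, n = 5) in vehicle, 1.61 ± 0.33 at 500 µM and 1.37 ± 0.22 at 5000 µM. At 48 h it was 1.24 ± 0.11 in vehicle, 1.86 ± 0.12 at 500 µM and 1.21 ± 0.05 at 5000 µM. The 500 µM arrays lay above vehicle at 48 h by 0.62 and the 48 h vehicle arrays lay below the 24 h vehicle arrays (difference -0.53), each with exact permutation p = 0.00794, the smallest these arrays can give, and adjusted p = 0.0185. At 24 h the 5000 µM arrays lay below vehicle (difference -0.41, exact permutation p = 0.0476, adjusted p = 0.0833), and at 48 h the 5000 µM arrays differed from vehicle by -0.03 (exact permutation p = 0.579). The GAPDH ratio had the same order of groups at 48 h, at 0.11 ± 0.02 in vehicle, 0.26 ± 0.07 at 500 µM and 0.09 ± 0.03 at 5000 µM. Gene counts that moved by over 1.5 times with this ratio as a covariate, and the lists fixed beforehand that passed at 500 µM and 48 h or in vehicle over time, are also given below with it.

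**Figure D1:**
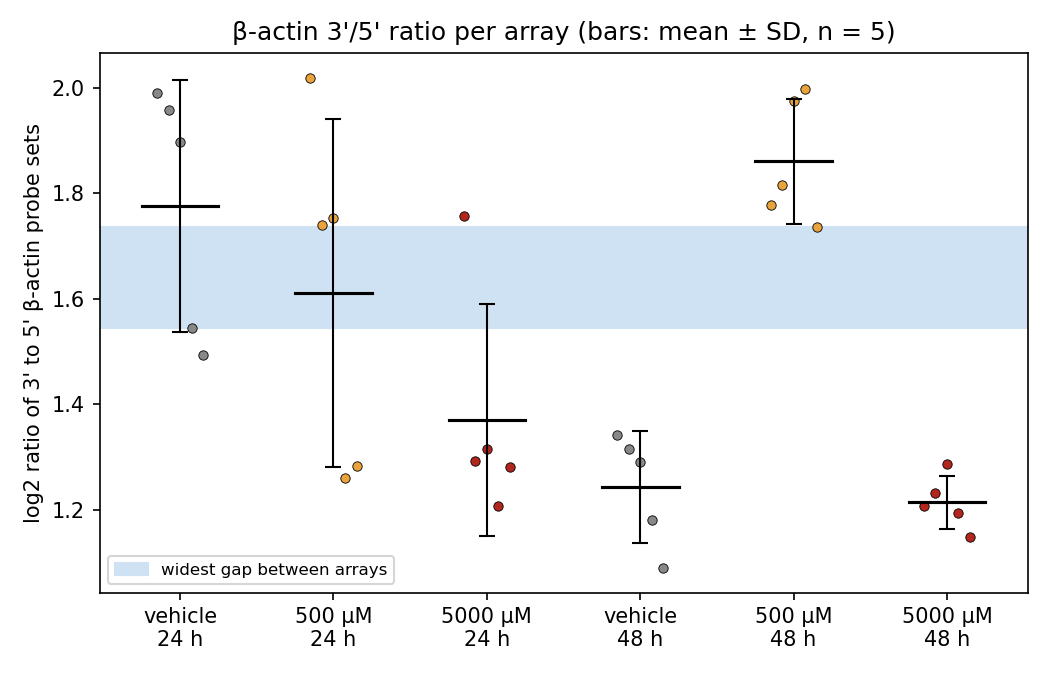
Log2 ratio of the 3' to the 5' β-actin probe sets on each array (points) with the mean ± SD of the 5 arrays of each group (bars), and the widest gap between arrays shaded. All 5 arrays of the 500 µM group at 48 h lie above the gap, and all 10 arrays of the vehicle and 5000 µM groups at 48 h lie below it.

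At 500 µM and 24 h, fatty acid oxidation genes rose. Cyp4a1, a fatty acid omega-hydroxylase, rose by 1.19 ± 0.11 on the log2 scale, and Ehhadh, the bifunctional enzyme of peroxisomal β-oxidation, by 1.03 ± 0.12. The mean signal of Cyp4a1 was 7170 ± 1477 (SD, n = 5) in vehicle and 16105 ± 1333 at 500 µM, and that of Ehhadh was 1957 ± 312 and 4016 ± 723. Of the 26 tested PPAR-alpha targets and fatty acid oxidation genes, 18 rose and none fell in limma over all genes, and 24 rose when adjusted over the list alone, a count given below for lists that passed camera against vehicle or in vehicle over time, where it differs. The list's median change was 0.28 (camera, adjusted p = 3.19e-38, and adjusted p = 4.51e-04 with an estimated correlation). Other members that rose were Pdk4, a kinase that inhibits pyruvate dehydrogenase (0.84 ± 0.08), Angptl4, an inhibitor of lipoprotein lipase (0.59 ± 0.06), and Fabp1, the liver fatty acid-binding protein (0.49 ± 0.06).

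Besides these, the largest rises at 500 µM and 24 h were those of Spc24, a kinetochore protein (1.03 ± 0.16), Serpine2, a serine protease inhibitor (0.91 ± 0.10), and the sulfotransferase Sult1c3 (0.88 ± 0.12). The largest falls were those of Ccn2, also called connective tissue growth factor (-1.02 ± 0.09), Scd2, a stearoyl-CoA desaturase (-1.01 ± 0.17), Gucy2c (-0.76 ± 0.10), Rab11fip5 (-0.75 ± 0.14) and Atosb (-0.63 ± 0.12). Apoa5, an apolipoprotein that lowers plasma triglycerides, fell by 0.44 on the log2 scale (SE 0.07). Ddit3, which encodes CHOP, rose by 0.39 ± 0.08, a call that was lost when arrays were centred on their medians.

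Further lists passed the camera test at 500 µM and 24 h with small shifts. The ATF4 and CHOP list had 4 of 30 members higher and a median of 0.07 (adjusted p = 2.82e-04, and adjusted p = 0.406 with an estimated correlation), with 8 higher and 2 lower when adjusted over the list alone. The cholesterol synthesis list had 2 of 20 members lower, 8 when adjusted over the list alone, and a median of -0.14 (adjusted p = 0.00341 in camera, and adjusted p = 0.446 with an estimated correlation). The dedifferentiation and cytoskeleton list had 2 of 24 lower, 4 when adjusted over the list alone, and a median of -0.09 (adjusted p = 0.00341 in camera, and adjusted p = 0.406 with an estimated correlation). The CAR and PXR list, genes induced through the xenobiotic receptors of those names, had 1 of 14 higher and a median of 0.07 (adjusted p = 0.0283 in camera, and adjusted p = 0.317 with an estimated correlation). For oxidative phosphorylation the median was 0.05 (adjusted p = 0.00159 in camera, and adjusted p = 0.653 with an estimated correlation) and for the proteasome 0.06 (adjusted p = 0.0342 in camera, and adjusted p = 0.739 with an estimated correlation). Of their 41 and 31 members, 0 were called in limma, and 3 were higher and 1 lower in each list at an unadjusted p under 0.05. The calls of the CAR and PXR, oxidative phosphorylation and proteasome lists were lost under quantile normalization, and that of the proteasome list also with the 3'/5' ratio as a covariate (adjusted p = 0.52 in camera).

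In all, limma called 244 of 8531 genes at 500 µM and 24 h, 141 higher and 103 lower, with 5 changed at least 2-fold. The count depended on scaling and on single arrays. It was 51 (43 higher, 8 lower) when arrays were centred on their medians, 100 when only the groups compared entered the fit, 447 (198 higher, 249 lower) with arrays above or below the gap in the 3'/5' ratio as a block, and between 116 and 290 when 1 array was left out. The fit to arrays below the gap alone, 2 against 2, called 278 (71 higher, 207 lower), of which 85 were shared in the same direction.

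At 5000 µM and 24 h the changes were larger and more numerous. Hamp, the iron-regulatory hormone hepcidin, rose by 2.38 ± 0.18, from a signal of 1804 ± 486 (SD, n = 5) to 9263 ± 1825. Inhbe, the hepatic activin βE subunit, fell by 2.89 on the log2 scale (SE 0.12), from 4047 ± 475 to 555 ± 123. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.99 (SE 0.19), from 1527 ± 403 to 387 ± 112, and Scd2 fell by 2.04 (SE 0.17), from 657 ± 106 to 164 ± 51.1. The signals of 387 and 164 lie under 469, the mean signal of the dimmest tested gene, so the sizes of both falls depend on background. The next brightest Scd2 probe set was at -0.06 (adjusted p = 0.899 in limma over all probe sets), and at -0.11 at 500 µM and 24 h. Cyp2e1, a main oxidase of acetaminophen, rose by 0.79 ± 0.11, from 7347 ± 955 to 12600 ± 827.

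**Figure D2:**
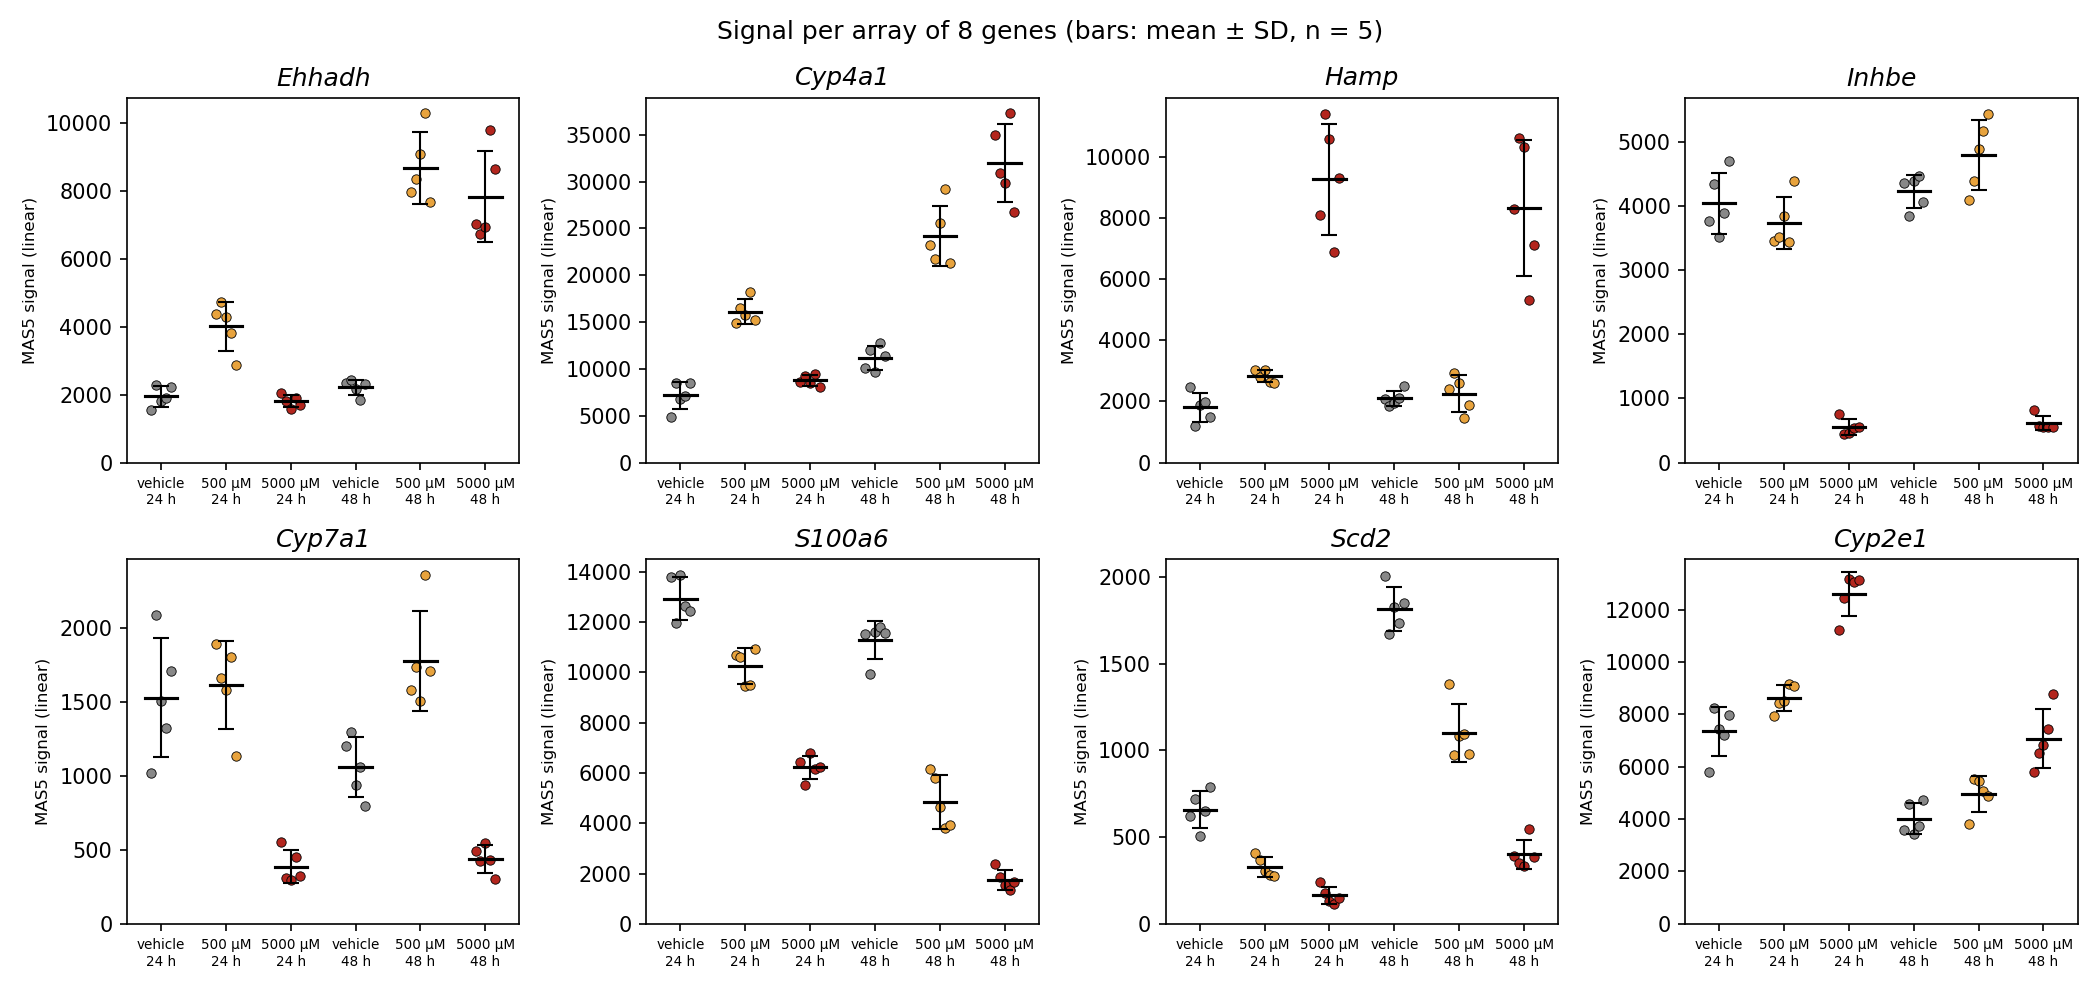
Deposited MAS5 signal (linear scale) of 8 genes on each array (points), with the mean ± SD of the 5 arrays of each group (bars). Inhbe, Cyp7a1 and Scd2 were low and Hamp was high at 5000 µM at both times, while Ehhadh was 1808 ± 177 at 5000 µM and 24 h against 7836 ± 1345 at 48 h.

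The other large rises at 5000 µM and 24 h included the histone gene Hist4h4 (1.62 ± 0.20), Serpine2 (1.58 ± 0.10), the protein kinase A inhibitor Pkib (1.53 ± 0.17), Hexim1, an inhibitor of the elongation factor P-TEFb (1.52 ± 0.09). Ptpn18 (1.41 ± 0.12), Cib2 (1.38 ± 0.10), Sh3gl3 (1.34 ± 0.17) and Gpr108 (1.32 ± 0.17) rose too. The other large falls included Poteml2 (-2.47 ± 0.10), the olfactory receptor gene Olr59 (-2.41 ± 0.35), the peroxisomal glycolate oxidase Hao1 (-2.20 ± 0.13) and the related Hao2 (-2.10 ± 0.12), the sulfotransferase Sult2a6 (-2.12 ± 0.23), Hsd3b5 (-2.04 ± 0.15) and the mitochondrial carbonic anhydrase Car5a (-2.02 ± 0.10).

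The urea cycle and amino acid list and the bile acid list were lower at 5000 µM and 24 h. In the urea cycle and amino acid catabolism list 23 of 34 members fell and 1 rose, and 25 fell when adjusted over the list alone, with a median of -0.39 (adjusted p = 1.65e-09 in camera, and adjusted p = 0.0451 with an estimated correlation). Among them were Haao, of the kynurenine pathway (-1.48 ± 0.10), Aass, of lysine catabolism (-1.44 ± 0.12), Hgd, of tyrosine catabolism (-1.21 ± 0.06), and Amt, of the glycine cleavage system (-1.03 ± 0.07). In the bile acid synthesis and transport list 12 of 17 fell and 2 rose, with a median of -0.62 (adjusted p = 1.96e-05 in camera, and adjusted p = 0.17 with an estimated correlation). The uptake carriers Slco2b1 (-1.24 ± 0.13) and Slc10a1 (-1.04 ± 0.11) and the bile salt export pump Abcb11 (-0.85 ± 0.10) fell beside Cyp7a1.

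Lipid synthesis lists fell as well. For cholesterol synthesis 13 of 20 members fell, 14 when adjusted over the list alone, with a median of -0.36 (adjusted p = 1.48e-04 in camera, and adjusted p = 0.391 with an estimated correlation). Squalene synthase, Fdft1 (-0.52 ± 0.07), Pmvk (-0.48 ± 0.08) and Insig1 (-0.43 ± 0.08) were among them. For fatty acid synthesis 11 of 21 fell, 12 when adjusted over the list alone, with a median of -0.19 (adjusted p = 2.82e-04 in camera, and adjusted p = 0.307 with an estimated correlation). These included Pklr, the liver pyruvate kinase (-1.13 ± 0.12), and Nr1h3, the oxysterol receptor LXR-alpha (-0.99 ± 0.08). In the PPAR-alpha list 13 of 26 rose and 2 fell, with a median of 0.18 (adjusted p = 0.00156 in camera, and adjusted p = 0.446 with an estimated correlation). Pdk4 rose by 1.31 ± 0.08, Angptl4 by 1.15 ± 0.06, Cpt1a, which carries fatty acids into mitochondria, by 0.78 ± 0.10 and Pex11a by 0.61 ± 0.05. Fabp1 fell (-1.31 ± 0.06) and the Ehhadh value was -0.10 ± 0.12 (adjusted p = 0.539 in limma).

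Genes of drug metabolism fell too. Of 18 other cytochrome P450 enzymes 11 fell and 2 rose, 12 and 2 when adjusted over the list alone, with a median of -0.42 (adjusted p = 0.00207 in camera, and adjusted p = 0.305 with an estimated correlation). Cyp4f1 (-0.94 ± 0.09), Cyp2c11 (-0.70 ± 0.12) and Cyp2d2 (-0.52 ± 0.07) fell, against the rise of Cyp2e1. Of 14 glucuronidation and sulfation genes 8 fell, with a median of -0.20 (adjusted p = 0.00159 in camera, and adjusted p = 0.28 with an estimated correlation), among them Ugt2b1 (-1.17 ± 0.10) and Ugt2b10 (-1.09 ± 0.07). Of 14 CAR and PXR targets 7 fell and 2 rose, 8 and 2 when adjusted over the list alone, with a median of -0.28 (adjusted p = 0.0139 in camera, and adjusted p = 0.297 with an estimated correlation). The uptake carrier Slco1a4 (-1.42 ± 0.18) and Cyp3a18 (-0.58 ± 0.06) fell. Of 22 glutathione transferases and peroxidases 10 fell and 1 rose, with a median of -0.14 (adjusted p = 0.0256 in camera, and adjusted p = 0.541 with an estimated correlation). Gsta3 (-0.67 ± 0.05) and Gstm4 (-0.67 ± 0.05) fell and Gstm7 rose (0.43 ± 0.10).

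The ATF4 and CHOP and the NRF2 lists were lower at 5000 µM and 24 h. Of 30 ATF4 and CHOP genes 14 fell and 4 rose, with a median of -0.17 (adjusted p = 0.0283 in camera, and adjusted p = 0.653 with an estimated correlation). Aldh1l2 (-1.25 ± 0.11), of mitochondrial folate metabolism, and the pseudokinase Trib3 (-0.58 ± 0.15) fell, and the stress-induced cytokine Gdf15 rose by 1.21 ± 0.15. Of 23 NRF2 targets, genes induced by electrophiles, 10 fell and 1 rose, with a median of -0.11 (adjusted p = 0.0436 in camera, and adjusted p = 0.446 with an estimated correlation). That call was lost under quantile normalization. Hmox1, heme oxygenase 1, fell (-0.33 ± 0.08), and the values of Nqo1 (0.12 ± 0.07), Txnrd1 (0.05 ± 0.09), Srxn1 (-0.02 ± 0.07) and Gclm (0.02 ± 0.07) did not pass the test. A second Txnrd1 probe set was at 0.54 (adjusted p = 0.00129 in limma over all probe sets). Of 28 ribosome biogenesis genes 14 fell and 1 rose, 16 and 1 when adjusted over the list alone, with a median of -0.28 (adjusted p = 0.00341 in camera, and adjusted p = 0.406 with an estimated correlation). Of 24 dedifferentiation and cytoskeleton genes 8 fell and 2 rose, with a median of -0.08 (adjusted p = 0.0161 in camera, and adjusted p = 0.446 with an estimated correlation).

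In limma, 3252 genes were called at 5000 µM and 24 h, 1583 higher and 1669 lower, of which 128 changed at least 2-fold (36 higher, 92 lower). With arrays centred on their medians the split was 809 higher and 1745 lower, and with the mean of all probe sets of a gene 1631 and 1396. The 3'/5' ratio was lower at this dose (difference -0.41), and with it as a covariate 2602 genes were called, 2242 of them called in the same direction without it. All 13 lists above were past the threshold with the covariate too.

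At 500 µM and 48 h the PPAR-alpha list was again higher. Ehhadh rose by 1.97 ± 0.12, from a signal of 2219 ± 224 (SD, n = 5) in vehicle to 8684 ± 1047, and Cyp4a1 was 11182 ± 1313 in vehicle and 24197 ± 3239 at 500 µM. Of 26 list members 21 rose and none fell, with a median of 0.37 (adjusted p = 1.45e-11 in camera, and adjusted p = 0.079 with an estimated correlation). Pdk4 (0.90 ± 0.08), Cpt1a (0.64 ± 0.10), Angptl4 (0.50 ± 0.06) and Fabp1 (0.49 ± 0.06) rose. With the 3'/5' ratio as a covariate 17 of the 26 rose and none fell, and the median was 0.39 (adjusted p = 1.03e-27 in camera). Among the falls that passed with and without the covariate were those of the calcium-binding protein S100a6 (-1.24 ± 0.12), Exoc1, of the exocyst complex (-1.24 ± 0.16), the small heat shock protein Cryab (-0.95 ± 0.10), Apoa5 (-0.94 ± 0.07), the aldo-keto reductase Akr1b8 (-0.83 ± 0.13) and Scd2 (-0.73 ± 0.17). S100a6 had a signal of 11284 ± 773 in vehicle and 4857 ± 1073 at 500 µM.

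Most other calls at 500 µM and 48 h were lost with the 3'/5' ratio as a covariate, and the ratio was higher in this group by 0.62. All 5 of its arrays lay above the gap and all 5 vehicle arrays below it. Ratio and dose therefore cannot be told apart within this comparison. Without the covariate limma called 3632 genes, 2044 higher and 1588 lower, 32 of them changed at least 2-fold. With the covariate it called 339, 323 of which were called in the same direction without it, and with arrays above or below the gap as a block 484. With arrays centred on their medians the split was 2324 higher and 432 lower, and the median change of all tested genes was 0.10 (0.01 as deposited). With the mean of all probe sets of a gene it was 1440 higher and 1653 lower. Several of the largest changes lost their calls with the covariate, namely the rises of Bcar1, a focal adhesion adaptor (2.44 ± 0.48), and Ptov1 (1.33 ± 0.34) and the falls of Entr1 (-1.60 ± 0.27), Tti2 (-1.25 ± 0.26) and Actr2-ps1 (-1.17 ± 0.29). The rises of C8h15orf39 (1.63 ± 0.21) and the receptor Lrp1 (1.28 ± 0.16) were called in both fits.

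The other lists past the threshold at 500 µM and 48 h stood beside this ratio. Bile acid synthesis and transport had 9 of 17 members higher, including Abcb11 (0.78 ± 0.10) and Cyp7a1 (0.75 ± 0.19), with a median of 0.27 (adjusted p = 0.0256 in camera, and adjusted p = 0.446 with an estimated correlation). With the covariate 1 of its members, Abcb11, was called and the median was 0.17, while the list passed (adjusted p = 0.00407 in camera). Fatty acid synthesis had 12 of 21 higher and 3 lower, with a median of 0.25 (adjusted p = 0.027 in camera, and adjusted p = 0.541 with an estimated correlation), a call lost with arrays centred on their medians. With the covariate 4 were higher and 1 lower, and the list passed (adjusted p = 0.00407 in camera). Its members included Elovl5, a fatty acid elongase (0.33 ± 0.06 for its brightest probe set and -0.23 as the mean of its probe sets). The circadian clock list had 7 of 13 higher, such as Nr1d2, a repressor of the clock (0.54 ± 0.09), with a median of 0.27 (adjusted p = 0.0256 in camera, and adjusted p = 0.446 with an estimated correlation). The covariate ended that call (adjusted p = 0.401 in camera) and that of Nr1d2.

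Other lists were lower at 500 µM and 48 h. Oxidative phosphorylation had 20 of 41 members lower and 2 higher, with a median of -0.15 (adjusted p = 1.14e-04 in camera, and adjusted p = 0.541 with an estimated correlation). Dedifferentiation and cytoskeleton had 14 of 24 lower and 1 higher, with a median of -0.20 (adjusted p = 1.72e-04 in camera, and adjusted p = 0.297 with an estimated correlation). Glutathione transferases and peroxidases had 7 of 22 lower, among them Gstm3 (-0.61 ± 0.07), with a median of -0.14 (adjusted p = 0.00137 in camera, and adjusted p = 0.406 with an estimated correlation). These 3 lists passed with the covariate, with 0, 4 and 2 members called lower. The proteasome list had 16 of 31 lower and 3 higher, 19 and 3 when adjusted over the list alone, with a median of -0.17 (adjusted p = 0.00111 in camera, and adjusted p = 0.541 with an estimated correlation). The covariate ended that call (adjusted p = 0.891 in camera). Without the filter on dim genes, marker medians here were -0.24 (Kupffer cells and leukocytes) and -0.27 (stellate cells and fibroblasts). They were -0.30 for cholangiocytes and 0.04 for endothelium.

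**Figure D3:**
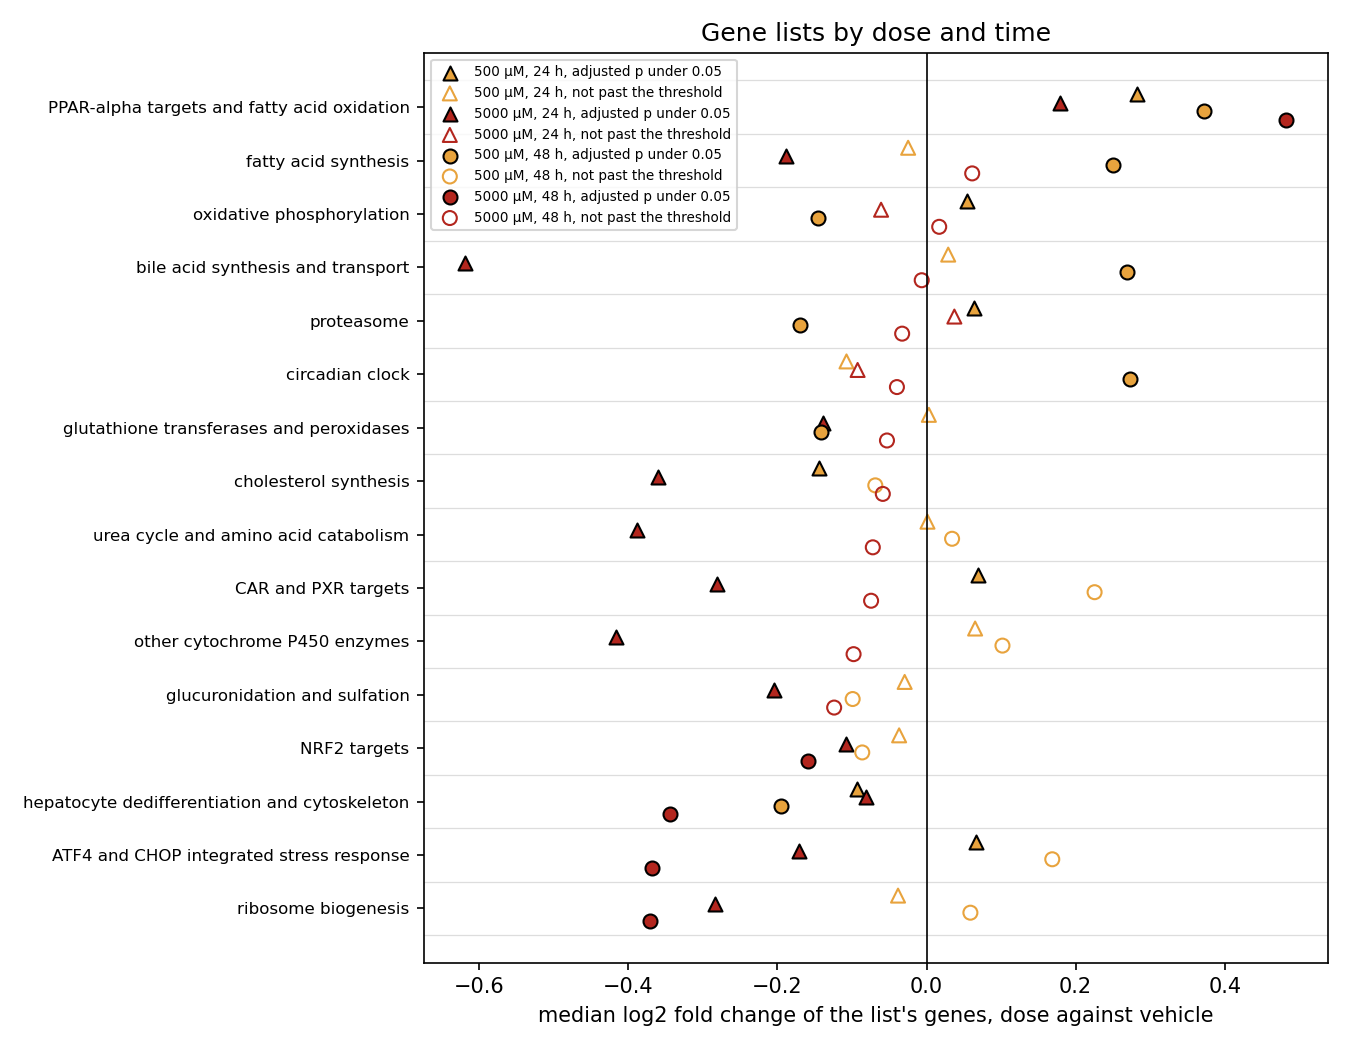
Median log2 fold change of each gene list's tested members against vehicle of the same time, for the 16 lists past the camera threshold in at least 1 comparison (filled symbols, adjusted p under 0.05). The PPAR-alpha list is to the right of 0 in all 4 comparisons, and the bile acid list is at -0.62 at 5000 µM and 24 h and 0.27 at 500 µM and 48 h.

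At 5000 µM and 48 h, where the 3'/5' ratio differed least from vehicle, the PPAR-alpha list was higher. The cytoskeleton, ribosome biogenesis, ATF4 and CHOP, and NRF2 lists were lower. Of these lower lists only the cytoskeleton list also passed with an estimated correlation. In the PPAR-alpha list 21 of 26 rose and 1 fell, 21 and 2 when adjusted over the list alone, with a median of 0.48 (adjusted p = 6.83e-16 in camera, and adjusted p = 0.0451 with an estimated correlation). Ehhadh rose by 1.81 ± 0.12, Cyp4a1 by 1.51 ± 0.11 to a signal of 31966 ± 4189 (SD, n = 5), Angptl4 by 1.06 ± 0.06 and Pex11a by 0.79 ± 0.05. Fabp1 was at -0.08 ± 0.06 (adjusted p = 0.36 in limma). Hamp rose by 1.95 ± 0.18 and Cyp2e1 by 0.82 ± 0.11, and Inhbe (-2.80 ± 0.12), Scd2 (-2.20 ± 0.17) and Cyp7a1 (-1.28 ± 0.19) fell, as at 24 h. The next brightest Scd2 probe set was at -0.57 here (adjusted p = 0.0263 in limma over all probe sets).

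In the dedifferentiation and cytoskeleton list, genes that rise when cultured hepatocytes flatten and lose their differentiated state, 16 of 24 members fell and none rose at 5000 µM and 48 h. The median was -0.34 (adjusted p = 2.05e-09 in camera, and adjusted p = 0.0451 with an estimated correlation). S100a6 fell by 2.71 on the log2 scale (SE 0.12) to 1755 ± 401, and Tagln2 (-1.56 ± 0.11), which binds actin, and the tropomyosin Tpm4 (-1.15 ± 0.07) fell with it. Markers of other liver cells had medians of -0.35 (Kupffer cells and leukocytes), -0.44 (cholangiocytes), -0.12 (stellate cells and fibroblasts) and 0.26 (endothelium) in this comparison, without the filter on dim genes. In the ribosome biogenesis list 19 of 28 fell, 21 when adjusted over the list alone, with a median of -0.37 (adjusted p = 2.07e-07 in camera, and adjusted p = 0.108 with an estimated correlation). Rrs1 (-0.76 ± 0.11), the transcription factor Myc (-0.74 ± 0.09) and Nop58 (-0.50 ± 0.08) were among those that fell. In the ATF4 and CHOP list 18 of 30 fell and none rose, with a median of -0.37 (adjusted p = 6.66e-06 in camera, and adjusted p = 0.305 with an estimated correlation). The cystine carrier Slc7a11 (-1.23 ± 0.10), Aldh1l2 (-1.08 ± 0.11), Trib3 (-0.84 ± 0.15), the translation repressor Eif4ebp1 (-0.69 ± 0.06) and Ddit3 (-0.42 ± 0.08) were among them, and Gdf15 was at 0.34 ± 0.15 (adjusted p = 0.088 in limma).

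In the NRF2 list 11 of 23 fell and 1 rose at 5000 µM and 48 h, 12 and 2 when adjusted over the list alone, with a median of -0.16 (adjusted p = 0.002 in camera, and adjusted p = 0.305 with an estimated correlation). Akr1b8 (-2.06 ± 0.13), the transcription factor Maff (-1.67 ± 0.11), Slc7a11, which is also in the ATF4 list, and Hmox1 (-0.48 ± 0.08) fell. Nqo1 (0.05 ± 0.07), Gclc (-0.04 ± 0.06), Srxn1 (-0.16 ± 0.07) and Gsr (-0.01 ± 0.13) did not pass the test. Single genes of other lists fell strongly, among them C9 (-1.47 ± 0.09) and C1s (-1.09 ± 0.06) of the complement system, Apoa5 (-1.38 ± 0.07), Cyp2c11 (-1.33 ± 0.12), Cyp4f1 (-1.19 ± 0.09), Cyp3a18 (-1.18 ± 0.06) and the phosphofructokinase Pfkp (-1.13 ± 0.18). The lists of other cytochrome P450 enzymes (8 of 18 lower, 4 higher, median -0.10, adjusted p = 0.077 in camera) and CAR and PXR targets (4 of 14 each way, median -0.07, adjusted p = 0.665 in camera) did not pass at this time. Neither did bile acid synthesis and transport (6 of 17 lower, 3 higher, median -0.006, adjusted p = 0.78 in camera) or the urea cycle and amino acid list (11 of 34 lower, 4 higher, median -0.07, adjusted p = 0.0536 in camera). The same held for glucuronidation and sulfation (5 of 14 lower, median -0.12, adjusted p = 0.0624 in camera), cholesterol synthesis (9 of 20 lower, 1 higher, median -0.06, adjusted p = 0.235 in camera) and fatty acid synthesis (4 of 21 each way, median 0.06, mean -0.07, test upward, adjusted p = 0.829 in camera).

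The other largest rises at 5000 µM and 48 h were those of Abhd15 (1.83 ± 0.17), Hist4h4 (1.76 ± 0.20), the GABA carrier Slc6a13 (1.63 ± 0.13), Hexim1 (1.38 ± 0.09), Gpr108 (1.23 ± 0.17), the linker histone H1f10 (1.23 ± 0.21) and Tmem132a (1.22 ± 0.13). The other largest falls were those of the metalloreductase Steap4 (-2.11 ± 0.23), Cyp2c12 (-2.10 ± 0.34), Sult6b2 (-1.88 ± 0.08), plasma prekallikrein, Klkb1 (-1.76 ± 0.15), Znf750 (-1.75 ± 0.21) and Wfdc21 (-1.73 ± 0.09). Limma called 2779 genes, 1243 higher and 1536 lower, and 117 changed at least 2-fold (25 higher, 92 lower). With the 3'/5' ratio as a covariate 3026 were called, 2777 of them in common and in the same direction.

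**Figure D4:**
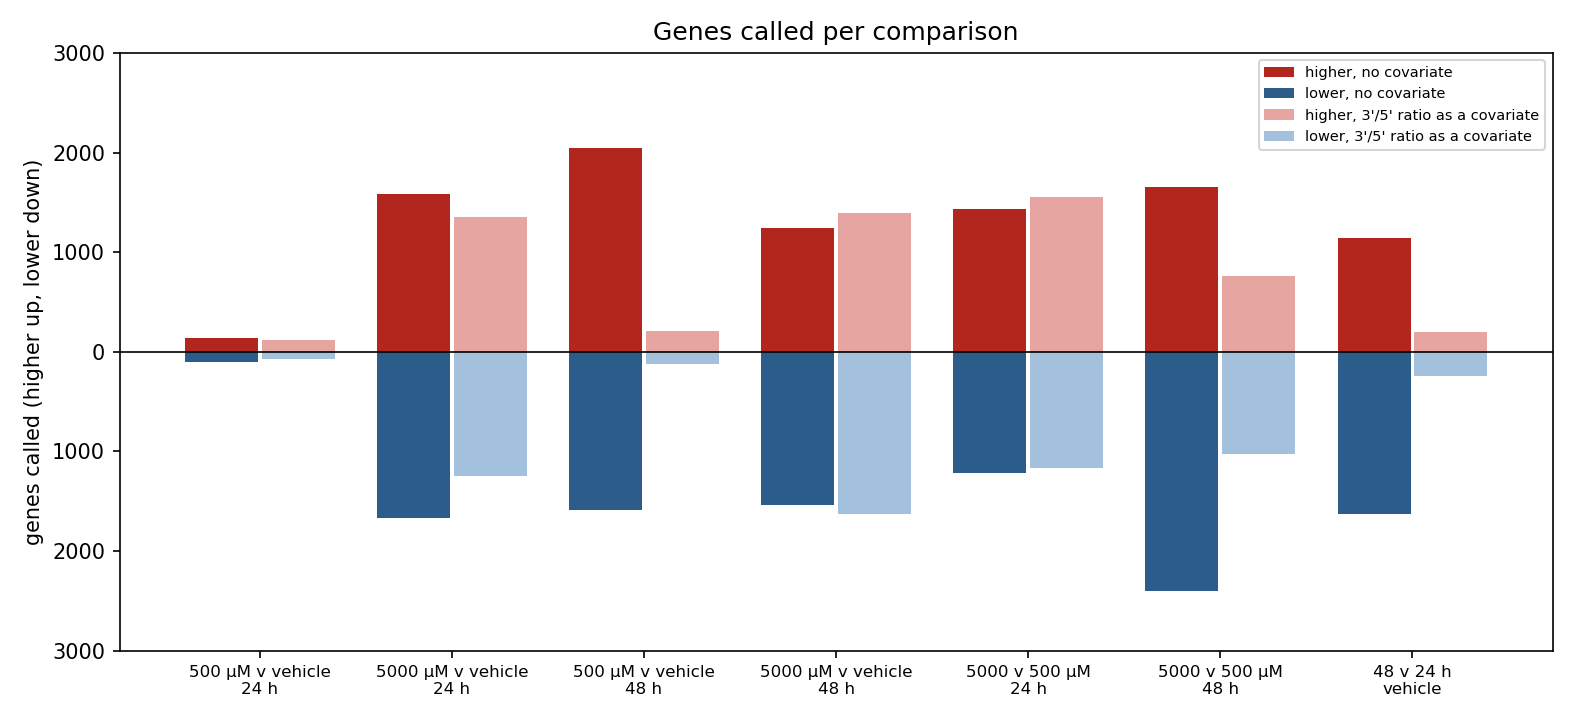
Number of genes called in limma per comparison, higher (upward bars) and lower (downward bars), without and with the β-actin 3'/5' ratio as a covariate. The covariate took the count at 500 µM and 48 h from 3632 to 339 and that at 5000 µM and 48 h from 2779 to 3026.

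Lists outside these groups did not pass the camera test against vehicle at either dose or time. At 5000 µM and 48 h the heat shock list had 1 of 17 members higher and 6 lower (median -0.11, adjusted p = 0.284 in camera), with Cryab at -0.64 ± 0.10. The p53 list had 1 of 15 higher and 5 lower (median -0.13, adjusted p = 0.164 in camera), with Ccng1, cyclin G1, at -0.94 ± 0.08. The endoplasmic reticulum chaperones had 5 of 23 higher and 2 lower (median 0.07, adjusted p = 0.245 in camera), with Calr, calreticulin, at 0.49 ± 0.08, against 1 higher and 8 lower at 5000 µM and 24 h (median -0.09, adjusted p = 0.067 in camera). Cell cycle genes had 2 of 9 higher and 2 lower (median -0.06, adjusted p = 0.817 in camera), and gluconeogenesis and glycolysis 3 of 20 each way (median -0.03, adjusted p = 0.905 in camera). Secreted hepatocyte proteins had 1 of 30 higher and 8 lower (median -0.03, adjusted p = 0.0577 in camera). Albumin itself, Alb, was at 0.03 ± 0.12. The liver-enriched transcription factors had 2 of 12 higher and 4 lower (median 0.03, mean -0.09, adjusted p = 0.78 in camera). Acute phase and complement genes had 2 of 24 higher and 8 lower, with a median of 0.02 while the mean of -0.12 and the direction of the test were negative (adjusted p = 0.129 in camera). The NF-kB list had 3 of 16 each way (median -0.001, adjusted p = 0.909 in camera), and metal response 2 of 8 higher and 1 lower (median 0.03, adjusted p = 0.777 in camera). AhR targets had 1 of 6 lower (median 0.03, adjusted p = 0.817 in camera), with Cyp1a1 at -0.14 ± 0.15.

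Markers of other liver cell types were mostly too dim to test as lists. In a fit without the filter on dim genes, the median vehicle signal at 24 h was 258 over 18 Kupffer cell and leukocyte markers, 302 over 18 stellate cell and fibroblast markers, 156 over 13 sinusoidal endothelial markers and 157 over 9 cholangiocyte markers. The members called by limma at 5000 µM and 48 h were 1 lower, 3 lower, 1 higher and 2 lower, in the same order. Lox, which crosslinks collagen (-0.83 ± 0.19), and smooth muscle actin, Acta2 (-0.47 ± 0.14), were lower in the filtered fit.

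Comparing the doses directly at 24 h, Hamp (1.69 ± 0.18), Apeg3 (1.51 ± 0.12) and Hist4h4 (1.46 ± 0.20) were higher at 5000 than at 500 µM, and Inhbe (-2.77 ± 0.12), Olr59 (-2.66 ± 0.35) and Sult2a6 (-2.61 ± 0.23) were lower. At 48 h Hist4h4 (2.17 ± 0.20), Hamp (1.89 ± 0.18) and Hexim1 (1.61 ± 0.09) were higher and Inhbe (-2.98 ± 0.12) and Cyp7a1 (-2.03 ± 0.19) were lower. Limma called 2659 genes at 24 h (1437 higher, 1222 lower) and 4064 at 48 h (1657 higher, 2407 lower). With arrays centred on their medians the splits were 592 and 1224, and 760 and 2708, and the median change of all genes at 48 h was -0.13. The 3'/5' ratio was lower at 5000 than at 500 µM at 48 h (difference -0.65, exact permutation p = 0.00794), and with it as a covariate 1782 genes were called.

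A small set of genes was called in the same direction at both doses and both times, 34 higher and 11 lower. With the covariate 20 and 4 of them were called in all 4 comparisons. Those 20 included Pdk4, Angptl4, Pex11a, the acyl-CoA dehydrogenase Acadvl, and the carnitine acyltransferases Crat and Crot, and the 4 were Scd2, Apoa5, the intermediate filament vimentin, Vim, and Pmp22. Txnip, an inhibitor of thioredoxin, was also among the 20 and rose by between 0.24 and 0.96. Pex11a at 500 µM and 48 h was at -0.012 as the mean of its probe sets. Acadvl, Crat, Crot, Vim, Pmp22 and Txnip were chosen after their values were seen.

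Across genes, which are not independent replicates, the log2 changes of the 2 doses correlated at r = 0.46 at 24 h and 0.31 at 48 h. Because the doses share their vehicle arrays, simulated unchanged groups gave r = 0.50 at both times. The covariance was 0.0260 at 24 h against 0.0068 simulated and 0.0298 at 48 h against 0.0068. With the vehicle arrays split between the doses r was 0.29 and 0.23. At 24 h 84 genes were higher at both doses (26.2 for independent lists), 79 were lower at both (20.2) and 13 were opposite. At 48 h the counts were 498 (298), 532 (286) and 344. The doses share their vehicle arrays, so their lists are not independent, and these excesses alone do not show a common response. Between the times, which share no arrays, the 5000 µM changes correlated at r = 0.57, with 670 genes higher at both (231 for independent lists), 797 lower at both (301) and 128 opposite. The 500 µM changes correlated at r = -0.28 between the times, with a jackknife SE of 0.24 over arrays. This was -0.02 with the 3'/5' ratio as a covariate, -0.082 with the block and -0.084 with no filter on dim genes. At 500 µM 67 genes were higher at both times (33.8 for independent lists), 15 lower at both (19.2) and 55 opposite. With the covariate 53 were called in the same direction at both times and 1 in opposite directions.

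In vehicle wells, 48 against 24 h, the skeletal actin gene Acta1 (1.86 ± 0.18), Serpine2 (1.61 ± 0.10), Tsx (1.57 ± 0.16), the fatty acid translocase Cd36 (1.52 ± 0.20) and Scd2 (1.48 ± 0.17) rose. Bcar1 (-3.05 ± 0.48), corticosteroid-binding globulin, Serpina6 (-1.83 ± 0.19), Cyp2c13 (-1.59 ± 0.08), Serpina3c (-1.58 ± 0.10) and Cyp1a2 (-1.45 ± 0.12) fell. The 3'/5' ratio also differed in this comparison (difference -0.53). Which of these named genes kept their calls with it as a covariate is not given here. Their changes therefore cannot be assigned to culture time alone. Bcar1 lost its call with the covariate at the lower dose against vehicle at 48 h, and in each difference between times. Of 18 other cytochrome P450 enzymes 10 fell and none rose, with a median of -0.35 (adjusted p = 4.85e-05 in camera, and adjusted p = 0.161 with an estimated correlation). Of 14 CAR and PXR targets 7 fell and 1 rose (median -0.18, adjusted p = 0.00828 in camera, and adjusted p = 0.288 with an estimated correlation). Of 17 bile acid genes 7 fell and none rose (median -0.23, adjusted p = 0.0131 in camera, and adjusted p = 0.431 with an estimated correlation). Acute phase and complement had 11 of 24 lower and 1 higher (median -0.09, adjusted p = 0.0355 in camera, and adjusted p = 0.518 with an estimated correlation). Higher lists were oxidative phosphorylation, with 13 of 41, or 12 when adjusted over the list alone (median 0.12, adjusted p = 2.04e-04 in camera, and adjusted p = 0.518 with an estimated correlation). So were glutathione transferases and peroxidases, with 9 of 22 higher, 10 when adjusted over the list alone, and 1 lower (median 0.12, adjusted p = 7.29e-04 in camera, and adjusted p = 0.431 with an estimated correlation). The PPAR-alpha list had 12 of 26 higher, 13 when adjusted over the list alone, and 4 lower (median 0.17, adjusted p = 0.0039 in camera, and adjusted p = 0.441 with an estimated correlation). The cytoskeleton list had 8 of 24 higher and 3 lower (median 0.14, adjusted p = 0.0178 in camera, and adjusted p = 0.441 with an estimated correlation).

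The circadian clock list was lower in 8 of 13 members between 24 and 48 h in vehicle, 9 when adjusted over the list alone (median -0.36, adjusted p = 0.00222 in camera, and adjusted p = 0.431 with an estimated correlation). The proteasome list was higher in 10 of 31, 11 when adjusted over the list alone, and lower in 3 (median 0.13, adjusted p = 0.00563 in camera, and adjusted p = 0.541 with an estimated correlation). Both lost their calls with the 3'/5' ratio as a covariate (adjusted p = 0.0573 and 0.724 in camera). The other lists passed with it, with fewer members called. These were 6 lower of the other cytochrome P450 enzymes, 3 lower of the bile acid list, 5 lower and 1 higher of the CAR and PXR list, and 6 lower and 1 higher of the acute phase list. They were 4 higher of the PPAR-alpha list, 3 higher of the cytoskeleton list, 5 higher and 1 lower of the glutathione transferases and peroxidases, and none of oxidative phosphorylation. Limma called 2770 genes over time in vehicle, 1145 higher and 1625 lower. With arrays centred on their medians the split was 284 and 1746, and with the mean of all probe sets of a gene 1166 and 1111. The ratio was lower at 48 h by 0.53, and with it as a covariate 440 genes were called, 399 of them in common and in the same direction. A fit to arrays below the gap alone (5 at 48 h and 2 at 24 h) called 1266.

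The effect of 5000 µM differed between the times for 1399 genes in limma, 660 more positive and 739 more negative at 48 h. Ehhadh (1.92 ± 0.17) and Slc6a13 (1.54 ± 0.18) had more positive changes at 48 h, as did Sult2a6 (1.81 ± 0.33). S100a6 (-1.66 ± 0.16), the stress-responsive gene Ndrg1 (-1.41 ± 0.22), the interferon-induced Ifitm3 (-1.32 ± 0.15) and the histocompatibility gene RT1-CE5 (-1.31 ± 0.16) had more negative ones. The bile acid list's changes were 0.49 more positive at 48 h in the median (adjusted p = 4.31e-06 in camera, and adjusted p = 0.0835 with an estimated correlation). Those of the urea cycle and amino acid list were 0.28 more positive (adjusted p = 3.65e-07 in camera, and adjusted p = 0.0835 with an estimated correlation) and those of the PPAR-alpha list 0.24 (adjusted p = 1.80e-07 in camera, and adjusted p = 0.0835 with an estimated correlation). With arrays centred on their medians 615 genes were called, 441 more positive and 174 more negative, and with the 3'/5' ratio as a covariate 821. For 500 µM the effect differed between the times for 3126 genes, 1886 more positive and 1240 more negative at 48 h, and for 3 with the covariate. The mean of all probe sets of a gene gave 1294 and 1332. Centring arrays on their medians gave 1831 and 273, with a median change of all genes of 0.12.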

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

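Some tests were chosen only after the results they bear on had been seen. These were the tests with the 3'/5' ratio as a covariate and those of scaling in the patterns weighed. The tests of each list's change in vehicle wells were also among them. So was the change predicted from the 24 h slopes for the ATF4 and CHOP list and the NRF2 list.

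Of 66 groups of 5 values (11 measures in 6 groups), 6 held a single array far from the other 4 by Dixon's criterion, which chance alone meets in about 1 of 20 groups. The β-actin 3'/5' ratio of replicate 1 at 5000 µM and 24 h was 1.76 against 1.21 to 1.31 in the others. The median signal of replicate 1 of the 24 h vehicle group was 400.7 against 315 to 340. Among single genes, Inhbe was 815 in replicate 1 at 5000 µM and 48 h (others 553 to 578) and Cyp7a1 was 2358 in replicate 4 at 500 µM and 48 h (1502 to 1737). S100a6 was 9915 in replicate 2 of the 48 h vehicle group (11525 to 11804) and Scd2 was 544 in replicate 4 at 5000 µM and 48 h (331 to 390).

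The effect of 500 µM differed between 48 and 24 h for 3126 genes in limma (Benjamini-Hochberg adjusted p under 0.05), and for 3 with the 3'/5' ratio as a covariate. The largest differences on the log2 scale were those of Bcar1 (3.62), Ptov1 (2.50), Plekhm2 (1.72), C8h15orf39 (1.67) and Nfic (1.59), and those of Entr1 (-1.95), Tti2 (-1.89), Actr2-ps1 (-1.78), Cds2 (-1.41) and Mug1 (-1.38), all of which lost their calls with the covariate. Lists that differed in camera were glutathione transferases and peroxidases (median -0.15), oxidative phosphorylation (-0.20), the proteasome (-0.22) and the circadian clock (0.38), with adjusted p from 1.49e-05 to 0.0113, and adjusted p = 0.919 for each with an estimated correlation. The proteasome and clock lists lost their calls with the covariate.

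The effect of 5000 µM differed between the times for 1399 genes in limma. The largest differences were those of Bcar1 (2.59), Ehhadh (1.92), Sult2a6 (1.81), Slc6a13 (1.54) and Olr59 (1.52), and those of S100a6 (-1.66), Cyp2c12 (-1.61), Ndrg1 (-1.41), Ifitm3 (-1.32) and RT1-CE5 (-1.31), of which Bcar1, Olr59 and Cyp2c12 lost their calls with the covariate. Lists with more positive changes at 48 h in camera were endoplasmic reticulum chaperones (median difference 0.15), cholesterol synthesis (0.19), fatty acid synthesis (0.29), PPAR-alpha targets (0.24), bile acid synthesis and transport (0.49), urea cycle and amino acid catabolism (0.28) and metal response (0.30). Lists with more negative changes were ATF4 and CHOP (-0.15), p53 targets (-0.28) and the cytoskeleton list (-0.25). Adjusted p in camera ran from 1.80e-07 to 0.0483, and from 0.0835 to 0.462 with an estimated correlation. The ATF4 and CHOP list lost its call with the covariate (adjusted p = 0.105 in camera).

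Signals outside the main measurement also differed between groups. The β-actin 3'/5' ratio was higher at 500 µM than in vehicle at 48 h by 0.617. Of 4151 tested probe sets without a listed gene, 549 were called at 5000 µM and 48 h, 360 higher and 189 lower. Over all 18626 probe sets tested 3900 were called there, which is a larger share.

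The number of genes called at 500 µM and 48 h, 3632 against 244 at 24 h, was weighed first. If RNA quality made those differences, each gene's slope on the 3'/5' ratio within the 15 arrays at 24 h should predict its change at 48 h, and it did over the called genes (Pearson r = 0.817 across genes, 0.684 over all genes, same sign for 90.4%). With the ratio as a covariate the called genes' median size went from 0.35 (median SE 0.09) to 0.19 (median SE 0.11), so calls ended through smaller changes and wider errors, and RNA quality, or a processing factor that went with it, is a likely source of much of this breadth. At 24 h in vehicle and at 500 µM, title-order replicates 1 to 3 lay above the gap and 4 and 5 below. The slope therefore does not separate RNA quality from processing order there. Of 2044 higher calls 1791 were shared with quantile normalization and 2013 with median centring, and of 1588 lower ones 1483 and 432. Centring raised the median change of all tested genes from 0.01 to 0.10. It thus had to keep the higher calls and could not test scaling for them. Scaling could account for the lower calls in part, and stays open for the higher ones. RNA quality was argued against as the whole cause of the PPAR-alpha list's rise here, since its median was 0.39 with the covariate. A dose effect on RNA integrity itself stays open. Sets of title numbers as a block left 3814 genes called, but each set holds 1 array of every group. Such a block cannot change a fold change, so this count decides nothing about RNA quality.

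The fall of the ATF4 and CHOP list and the NRF2 list at 5000 µM and 48 h was weighed next. RNA quality, as far as the ratio measures it, was argued against, since the ratio differed by -0.03 between these groups. The slopes on the ratio at 24 h then predict a median change of 1.86e-04 (quartiles -0.0037 to 0.0058) for the 52 members, against -0.25 seen. With so small a ratio difference the prediction had to lie near 0, so it adds little to that difference. The list median nearest 0 under another scaling was -0.16. These scalings barely moved the comparison, with a median change of all genes of -0.011 as deposited, -0.009 with quantile normalization and -0.010 with centring. They therefore cannot decide about scaling, which stays open. A rise in vehicle wells over time was argued against as the whole cause, since the 28 members that fell, by a median of 0.43, rose in vehicle between 24 and 48 h by a median of 0.065 (upper quartile 0.12, 4 called higher), and 0 of them rose by as much as they fell. A smaller contribution from such a rise, and a dose effect as a hypothesis, stay open.

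The fall of the bile acid list and of the urea cycle and amino acid list at 5000 µM and 24 h, not called at 48 h (medians -0.006 and -0.07), was weighed last. RNA quality was argued against as the whole cause, since the median difference between the times was 0.31 for the bile acid list and 0.26 for the urea cycle and amino acid list with the covariate, or 62.0% and 92.1% of the differences without it. Vehicle wells declined between 24 and 48 h by a median of -0.23 in the bile acid list and -0.050 in the urea cycle and amino acid list, which is 45.9% of the difference (95% limits 9.84 to 179.6% over 2000 resamples of list members) and 17.9% (1.80 to 63.0%). Those limits measure the spread between list members and not between wells, and the vehicle arrays enter both parts of each share. The medians hold both a decline in vehicle wells and a rise at 5000 µM (median changes between the times at this dose of 0.13 and 0.18). How much of the narrowing came from each stays open here.

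Chance in the grouping of arrays is an unlikely source of each count of genes, since the real grouping was the 1 of 100 splits with a count as large. That is the smallest share 100 splits can give. The splits show only that the groups differ. They cannot tell dose from the 3'/5' ratio, which follows the groups at 500 µM and 48 h. The real counts and the highest of the other splits against vehicle were 244 and 3 at 500 µM and 24 h, 3632 and 1159 at 500 µM and 48 h, 3252 and 1614 at 5000 µM and 24 h, and 2779 and 746 at 5000 µM and 48 h. Between the doses they were 2659 and 1361 at 24 h and 4064 and 1481 at 48 h, and in vehicle over time 2770 and 615. For the differences between times they were 3126 and 1 at 500 µM and 1399 and 144 at 5000 µM. There the other splits exchanged times within vehicle and within the dose, on what a fit of dose plus time left over. Those other counts are therefore not of the same kind as the rest.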

How the results depend on the processing

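The alternatives that use the 3'/5' ratio (as a covariate, as a block of arrays above or below the gap, or arrays on one side of it) were chosen after seeing the data, and the others were fixed before.

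Of 370 called results of named genes, the covariate ended 81 calls and turned 3, the block ended 68 and turned 1, median centring ended 51, the mean of all probe sets ended 19 and turned 4, no filter ended 20, the fit to only the groups compared 16, quantile normalization 12, no intensity trend 10 and array weights 2. Adding 16 before log2 and sets of title numbers as a block ended none of them. Leaving out 1 array ended 45 calls at least once and turned 0. Of 33 list calls an estimated correlation ended 29 and no other setting more than 4.

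Counts more than 1.5 times from those reported follow, and the cause was not tested except for stricter thresholds, fewer arrays and every probe set, which follow from construction. Median centring gave 51 genes at 500 µM and 24 h and 615 for the 5000 µM difference between times, and the fit to only the groups compared gave 100 at 500 µM and 24 h. Every probe set gave 5544 (500 µM, 48 h), 5206 (5000 µM, 24 h), 6435 (between doses, 48 h) and 4693 (500 µM difference between times). The covariate gave 339 (500 µM, 48 h), 1782 (between doses, 48 h), 440 (vehicle over time), 3 (500 µM difference) and 821 (5000 µM difference). The block gave 447 (500 µM, 24 h), 484 (500 µM, 48 h), 2021 (between doses, 48 h), 1190 (vehicle over time) and 682 (500 µM difference). Adjusted p under 0.01 left 90 and 2340 at 500 µM (24 and 48 h), 1644 (vehicle over time), 1876 and 701 (500 and 5000 µM differences). A 1.5-fold minimum left 33, 440, 645 and 492 against vehicle (500 µM at 24 and 48 h, 5000 µM at 24 and 48 h), 465 and 806 between doses, 286 in vehicle over time, and 970 and 399 for the differences. Arrays below the gap gave 1266 in vehicle over time and arrays above it gave 31 at 500 µM and 24 h. Arrays on one side of the gap could not be compared at 500 µM and 48 h, between the doses at 48 h or for the 500 µM difference, and arrays above it only at 500 µM and 24 h. Of 33 list calls over the 4 comparisons of a dose with vehicle, an estimated correlation kept 4 and fry kept 30. In all, fry made 56 list calls.

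The correlation of the doses at 24 h was 0.38 with the covariate and 0.29 with vehicle arrays split, and at 48 h 0.39 with no filter and 0.23 with vehicle arrays split. That of the times was -0.024 at 500 µM with the covariate (-0.084 with no filter, -0.082 with the block), and at 5000 µM 0.34 with no filter and 0.63 with the covariate.

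Directions, including those of results not called as reported (Hspa5, Ddb2, Mdm2 and Elovl5 at 5000 µM), turned for Actr2-ps1 (0.082), Psmd4 (0.026) and Gsr (0.10, and 0.010 with the block) at 500 µM and 48 h with the covariate, and for Hspa5 there under quantile normalization (0.10). With the mean of all probe sets they turned for Ddb2 (-0.44) and Srebf2 (0.16) at 5000 µM and 48 h, Elovl5 at 5000 µM and 24 h (0.42), and Srebf2 (-0.33), Elovl5 (-0.23), Pex11a (-0.012) and Mdm2 (-0.35) at 500 µM and 48 h.

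Leaving out 1 array gave 116 to 290 genes at 500 µM and 24 h. The count was 155 and 156 without vehicle replicates 1 and 2, and 151 and 116 without 500 µM replicates 4 and 5. It was 3069 to 3509 at 500 µM and 48 h, and 2904 to 3379 and 2500 to 2608 at 5000 µM. Between doses it was 2392 to 2626 and 3613 to 3999, and in vehicle over time 2285 to 2658. For the differences it was 2642 to 3226 and 1105 to 1725, and there were 30 to 37 list calls.

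The labels carry no replicate numbers, so no pairing is known. Sets of 6 consecutive title numbers, each with 1 array of every group, gave 322 and 3814 genes at 500 µM (24 and 48 h) as a block. They moved no count by over 1.5 times. Being balanced over the groups, they could move counts only through the error, and not through the fold changes. Signal over background limits the dimmest 40% of genes, which were left out of the reported tests.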

Other observations

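The lists of histone, interferon-stimulated, peroxisomal and BMP pathway genes were written only after single genes of each kind had been seen to change. Those genes were left out of their tests.

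Histone genes rose at 5000 µM. Of 6 tested besides Hist4h4 and H1f10, 5 rose at 24 h, among them H2ax (1.25 ± 0.10), the linker histones H1f4 (0.83 ± 0.15) and H1f2 (0.72 ± 0.07) and H2az1 (0.73 ± 0.05). The list median was 0.72 (camera, Benjamini-Hochberg adjusted p = 4.05e-05, and adjusted p = 0.00691 with an estimated correlation). At 48 h 4 rose, with a median of 0.51 (adjusted p = 0.00074 in camera, and adjusted p = 0.019 with an estimated correlation). They were H1f2 (0.91 ± 0.07), H1f4 (0.67 ± 0.15), H2ax (0.66 ± 0.10) and H2az1 (0.36 ± 0.05). H2aj (0.07 ± 0.07) and Macroh2a1 (0.10 ± 0.12) did not pass the test at 48 h. The list was one of replication-independent and other histone genes. Most replication-dependent histone transcripts lack a poly(A) tail, so for any such member a change in polyadenylation may contribute to the signal. This was not tested, and it does not apply to the replication-independent members. The list was not split by kind, so its median cannot show how far the replication-independent members rose by themselves.

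Some interferon-stimulated genes fell at 5000 µM and 48 h. Rsad2 (-1.73 ± 0.18), Isg20 (-1.45 ± 0.10), Ifitm3 (-1.42 ± 0.11) and RT1-CE5 (-1.13 ± 0.11) fell. Of 34 others 13 fell and 4 rose, with Isg15 (-1.36 ± 0.18), Mx2 (-1.06 ± 0.20), Ifit2 (-0.87 ± 0.08) and the peptide transporter Tap1 (-0.60 ± 0.10) lower and Trim25 (0.47 ± 0.09) and Stat2 (0.35 ± 0.13) higher. The list median was -0.16 (adjusted p = 0.0293 in camera, and adjusted p = 0.173 with an estimated correlation), so whether the group moved as a whole cannot be told apart from a few correlated genes.

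Peroxisomal genes outside the PPAR-alpha list were tested because Pex11a, Abcd3, Crat and Crot rose at both doses and times, Pex11a by its brightest probe set (-0.012 as the mean of its probe sets at 500 µM and 48 h). At 500 µM and 24 h 15 of 46 rose and none fell (median 0.13, adjusted p = 2.28e-12 in camera, and adjusted p = 0.00691 with an estimated correlation). At 5000 µM and 48 h 19 rose and 4 fell (median 0.16, adjusted p = 0.000258 in camera, and adjusted p = 0.152 with an estimated correlation), with Hacl1 (0.86 ± 0.07), of phytanic acid breakdown, and Acot12 (0.86 ± 0.12) higher. At 5000 µM and 24 h 9 rose and 9 fell (adjusted p = 0.936 in camera), Hao1 and Acox2 (-1.45 ± 0.10) among those that fell. At 500 µM and 48 h 18 rose and 4 fell (median 0.15, adjusted p = 0.0326 in camera, and adjusted p = 0.391 with an estimated correlation), and adjusted p = 3.63e-06 in camera with the 3'/5' ratio as a covariate.

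The rise of Hamp at 5000 µM and 24 h was weighed against BMP and SMAD signalling, which drives hepcidin transcription. Of 8 other genes listed for this pathway, not all of them targets, Id2 (0.63 ± 0.10) and Bmp2 (0.44 ± 0.12) rose and Id4 (-0.64 ± 0.13) fell. The median was 0.09 (adjusted p = 0.693 in camera). At 48 h 2 rose and none fell, with a median of 0.21 (adjusted p = 0.18 in camera). Members too few, and moving both ways at 24 h, decide nothing here, and the source of the hepcidin change stays open.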
